A study of Mus musculus with 10 samples.

How the data were processed

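The series holds RNA-seq of mouse esophageal epithelium in 10 libraries, 5 from wild-type mice and 5 from tamoxifen-treated p63CreERT2;Mst1 loxP/loxP;Mst2-/- mice, called knockout here. Per the labels' protocols, muscle and mesenchyme were removed after Dispase digestion, total RNA was extracted from the epithelium, and libraries made with the VAHTS Universal V8 kit were sequenced as read pairs on an Illumina instrument. The authors deposited one table of FPKM values (fragments scaled by the length of the gene model and the total of the library, 2 decimals) with 56691 Ensembl mouse gene IDs and their symbols. Per the submitters' processing notes, cutadapt, HISAT2 2.0.1, HTSeq 0.6.1 and the build mm9 were used; their settings, the annotation release, the use of strand and the total used for scaling are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart. The symbol Mst1 in the table belongs to another gene, so the targeted kinases were taken by the symbols Stk4 and Stk3. No count table was used here, so no count model was fitted.

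Depth was estimated from the FPKM values of single-exon genes up to 1200 bp long, by finding the fragment total at which the values become whole numbers of fragments. With 1081 to 1315 genes per library, 98.3% to 99.2% of values were whole within 0.01 fragments beyond rounding, against 8.6% to 9.8% by chance, at totals of 13050000 to 16460000 fragments. Chromosomes, biotypes and the share of each gene's 31-base sequences found in another gene came from GENCODE M21 on GRCm38, which lists 52073 of the gene IDs and lacks 4618. As that build is not mm9, only chromosome names are given and no positions. Of the tested genes, 98.9% have a sequence share. Genes sharing at least 0.2 of their sequences are treated as uncertain; in an alternative they were left out.

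Values were tested as log2(FPKM + 1), so fold changes are on that scale, which understates changes of low genes. Genes with at least 1 FPKM in at least 5 libraries were kept, 11386 in all. The model was limma 3.58.1 in R 4.3.3 with genotype as the only term, empirical Bayes with trend and robust estimation, and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. All 10 libraries entered. Fold changes are knockout minus wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and depth and shared sequences were computed with numpy 2.4.6 and pandas 2.3.3.

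Before the data were examined, the model, the alternatives, the rule for naming genes and 33 gene lists with 783 genes were fixed, all of which were found. Of these lists 23 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists, with the correlation estimated from the data, fry and an exact two-sided permutation test of the list mean as alternatives. The permutation test has 252 assignments and a smallest p of 0.0079, so that after adjustment over 23 lists a list at that p passes only if several lists have p-values near it. With the estimated correlation camera called 0 lists, and 1 had an unadjusted p under 0.05. Adjustment over the list alone is Benjamini-Hochberg within its members. The rule named the targeted genes, the 12 largest changes in each direction among genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group, leaving out predicted names and pseudogenes by their symbols (Sprr2g, a polymorphic pseudogene in GENCODE M21, stays in), up to 8 members of the 4 core lists and 4 of every other list by smallest p, and the most abundant member of each list of other cells. Genes outside that rule, chosen after their values were seen, are Krt13, Krt4, Krt5, Krt14, Krt15, Krt6a, Mki67, Dbp, Xist, the gene copies and their parents, the list members given in counts of called genes beyond those numbers, and the genes named only in the closing part. Some genes that would otherwise be named are not reported here.

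The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, scaling by median ratios and quantile normalization, empirical Bayes without trend and robust estimation, sample quality weights, the replicate number as a block, a covariate for mesenchymal and muscle markers, a covariate for Y-linked genes, other thresholds, and leaving out each library. In the latter the tested genes were kept as in the complete data. A covariate for clock output genes (Dbp, Nr1d1, Per3, Tef) and the exclusion of genes sharing sequence were added after seeing the data. Libraries were split by Dbp level, above and below 5 FPKM, only to repeat the genotype comparison within each class.

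The test was run on simulated data with the means and spread of the 11386 genes, 5 and 5 libraries and 200 changed genes. It recovered 32.2% of changes of 0.5 log2 units, 82.7% of changes of 1 and 97.6% of changes of 2, and 4.6% of calls were false. With Benjamini-Hochberg adjustment recovery depends on how many genes change, and 1465 genes were called in the real data. These rates are therefore not the recovery of the reported comparison. Camera with the preset correlation called a list of 40 changed genes in 5 of 5 runs and 0 of 100 unchanged lists; these simulated genes were independent, unlike real ones.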

Results

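RNA was sequenced from the esophageal epithelium of wild-type mice and of knockout mice, with 5 libraries in each group. The knockout mice were designed to lack the Hippo pathway kinases Mst1 and Mst2, which carry the gene symbols Stk4 and Stk3. The knockout combined Mst2 null alleles with an Mst1 allele flanked by loxP sites and a tamoxifen-inducible Cre recombinase named for p63, the transcription factor of squamous basal cells. Both groups had received tamoxifen at 100 mg/kg in 3 doses, every 2 weeks, and RNA was taken after about 8 weeks, so the groups are compared at equal treatment. Genotype here includes the Cre allele and the modified Mst1 and Mst2 alleles with their surroundings. Whether both groups share 1 genetic background is not settled. Effects of these cannot be separated from loss of the kinases in the comparisons below. Each library held 13050000 to 16460000 fragments and 10878 to 11606 genes at 1 FPKM or more. The suprabasal keratins Krt13 and Krt4 were abundant in all 10 libraries, at 33902 to 38781 FPKM and 22771 to 30280 FPKM. The Y-linked transcript Ddx3y lay between 15 and 26.1 FPKM in all libraries and Xist, the transcript of the inactive X chromosome, at no more than 0.02 FPKM. Pearson correlations of log2 values were 0.955 to 0.979 within wild type, 0.956 to 0.984 within knockout and 0.906 to 0.958 between the groups. The first principal component, with 45.7% of the variance, placed the wild-type libraries between -36.7 and -14.7 and the knockout libraries between 17.9 and 33.2. The labels do not state that each library is a separate mouse, so the p-values measure the spread between these samples.

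Transcript of Stk3 (ENSMUSG00000022329, chromosome 15), the gene of Mst2, fell to near the floor in every knockout library, and transcript of Stk4 (ENSMUSG00000018209, chromosome 2), the gene of Mst1, was still present. Stk3 went from 2.62 ± 0.521 FPKM in wild type to 0.134 ± 0.0862 FPKM in knockout (SD, n = 5 and 5), 94.9% lower. The highest knockout value was 0.25 FPKM and the lowest wild-type value 2.08 FPKM. Its log2 fold change was -1.67 (SE 0.12; limma, Benjamini-Hochberg adjusted p = 2.78e-06). Stk4 was at 19.3 ± 2.41 FPKM in wild type and 15.6 ± 2.00 FPKM in knockout, and the groups overlapped, with knockout values of 12.2 to 17.4 FPKM against 17.0 to 22.7 FPKM. The log2 fold change of Stk4, -0.29 (SE 0.12), did not pass the test (limma adjusted p = 0.123). A value summed over the whole gene cannot show a deletion of single exons, and the deleted exons are not given in the sources used here, so the Stk4 level is no check of the Mst1 deletion.

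**Figure D1:**
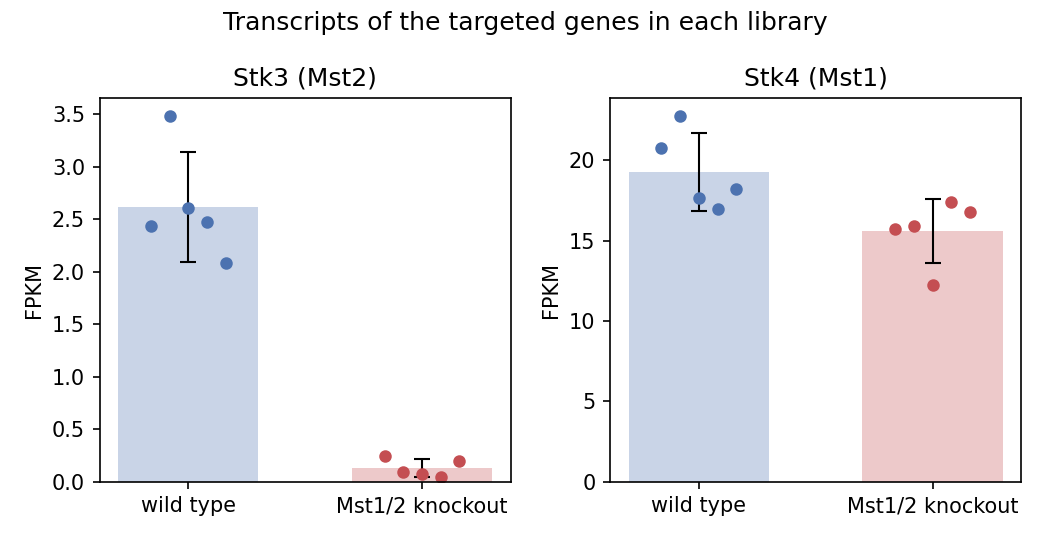
FPKM of Stk3 (left) and Stk4 (right) in each library (points), with the group mean (bar) and SD (line) of 5 wild-type and 5 Mst1/2 knockout libraries. All knockout values of Stk3 are at or below 0.25 FPKM, while those of Stk4, 12.2 to 17.4 FPKM, overlap the wild-type values.

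The epithelial transcriptome differed broadly between the genotypes. Among the genes with the largest increases were members of the small proline-rich protein family, which form the cornified envelope of squamous cells. Sprr2f rose from 4.39 ± 7.15 to 146 ± 103 FPKM (SD, n = 5 and 5), Sprr2g from 9.43 ± 14.2 to 216 ± 89.0 FPKM and Sprr2a3 from 8.38 ± 3.99 to 144 ± 51.9 FPKM. Pglyrp1, an antibacterial protein that binds peptidoglycan, went from 0.258 ± 0.264 to 35.0 ± 23.1 FPKM, the adhesion molecule Ceacam1 from 1.60 ± 1.25 to 18.2 ± 8.16 FPKM and the interferon-inducible Ifi202b from 24.5 ± 16.2 to 144 ± 17.3 FPKM. The proteinase inhibitor Spink12 rose from 0.168 ± 0.174 to 7.31 ± 1.38 FPKM, with a log2 fold change of 2.83 (SE 0.14; limma adjusted p = 9.47e-08). Without wild type 3 the wild-type means were 1.24 FPKM for Sprr2f, 3.16 FPKM for Sprr2g, 0.152 FPKM for Pglyrp1 and 0.107 FPKM for Spink12. The other genes with the largest increases were Sprr2h, Mal, Ces1f, Cstdc6 and S100a4. Of the genes that fell most, Fut2, a fucosyltransferase that makes the H antigen of secretions, went from 15.4 ± 1.13 to 0.12 ± 0.0866 FPKM, with a log2 fold change of -3.88 (SE 0.09; limma adjusted p = 2.24e-10). The NKG2D ligand H60c fell from 25.8 ± 6.92 to 0.054 ± 0.0695 FPKM (mean 0.025 FPKM without knockout 5), and Clec2g, a C-type lectin, from 11.1 ± 3.24 to 0.270 ± 0.145 FPKM. Apoe and Apoc1, lipoprotein genes that neighbour each other on chromosome 7, fell from 58.0 ± 18.1 to 4.14 ± 0.660 FPKM and from 50.9 ± 12.4 to 3.35 ± 0.791 FPKM. Lce1k, a late cornified envelope gene, fell from 142 ± 64.7 to 9.33 ± 6.39 FPKM, and Bpifa5 and Cyp2a5 also fell. Many of the largest changes lie on 2 chromosomes. Pglyrp1, Ceacam1, Fut2 and Cyp2a5 are on chromosome 7 like Apoe and Apoc1. Sprr2f, Sprr2g, Sprr2h, Sprr2a3, S100a4, Lce1k, Rps3a1 and Rpl34 are on chromosome 3, and the rest lie on other chromosomes. Whether genetic background plays a part in this was not tested. In all, 900 of 11386 tested genes were higher and 565 lower in knockout (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05), and 171 and 183 of these had an absolute log2 fold change of at least 1. Non-overlapping groups were found for 10.5% of tested genes, against 0.79% by chance.

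The ribosomal protein genes Rpl29, Rps3a1, Rpl34 and Rpl30 were also among those that fell most, and each has copies of similar sequence elsewhere in the genome. Rpl29 fell from 189 ± 41.3 to 1.36 ± 0.439 FPKM and Rpl34 from 64.0 ± 16.7 to 2.68 ± 0.477 FPKM, while the pseudogene Rpl34-ps1, named after its values were seen, rose from 52.5 ± 13.6 to 451 ± 99.0 FPKM. Rps3a1 was at 590 FPKM in knockout 2 and at a mean of 9.51 FPKM in the other knockout libraries, against 770 ± 186 FPKM in wild type. The share of 31-base sequences found in another gene was 0.491 for Rpl29, 0.769 for Rps3a1, 0.116 for Rpl34 and 0.186 for Rpl30, and also 0.736 for Sprr2a3, 0.585 for Cyp2a5, 0.581 for S100a4, 0.507 for Cstdc6 and 0.486 for Ceacam1. The values of all these genes are therefore uncertain in how reads were divided between copies. Of the other genes named, Frmd6, Dsg1a, Sprr2a1, Uhrf1, Stfa1, Phlda1, Oas1a, Me1, Gsta1, Acat2, Idi1, Eno1, Hspd1, Dbp, Krt14, Krt6a, Npm1, Lce1c, Ces1b, Capza1 and Eif3j1 also share at least 0.2 of these sequences with another gene and carry the same uncertainty. Of 801 tested pseudogenes, 104 were higher and 16 lower.

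The counts depended on the libraries and on the scaling. Higher and lower genes numbered 495 and 363 without wild type 1, 436 and 357 without wild type 5, 538 and 466 without knockout 1, 572 and 408 without knockout 3, and 529 and 369 without knockout 5. Higher genes made up 61.4% of the calls as reported, 45.5% after scaling by median ratios and 47.9% after quantile normalization. A score of fibroblast, endothelial and muscle markers was lower in knockout (0.36 ± 0.01 against 0.40 ± 0.04, mean log2 value, n = 5 and 5; exact permutation test, two-sided p = 0.0476), and with it as covariate limma called 179 genes higher and 181 lower. Most of the 80 markers in this score were too low to be tested, and it includes Dcn and Gsn, which are themselves called as lower. The score can therefore take up part of the genotype difference and is no clear measure of tissue composition. Of 109 called genes named here and in the additional observations, 73 kept their call without each single library, and between 9 calls (without knockout 4) and 33 (without wild type 5) ended when 1 library was left out. The 36 genes that lost their call in at least 1 such comparison were Axl, Bmp4, Calm4, Ccne1, Cldn1, Cldn4, Col17a1, Eno1, Fos, Frmd6, Gsn, Hmox1, Id1, Idi1, Il33, Ivl, Klk7, Krt78, Lama3, Lce1c, Mcm5, Melk, Npm1, Nsdhl, Pdpn, Pfkm, Phlda1, Rrm1, Sesn1, Skil, Sprr3, Tkt, Tnfrsf10b, Uhrf1, Wee1 and Xbp1.

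**Figure D2:**
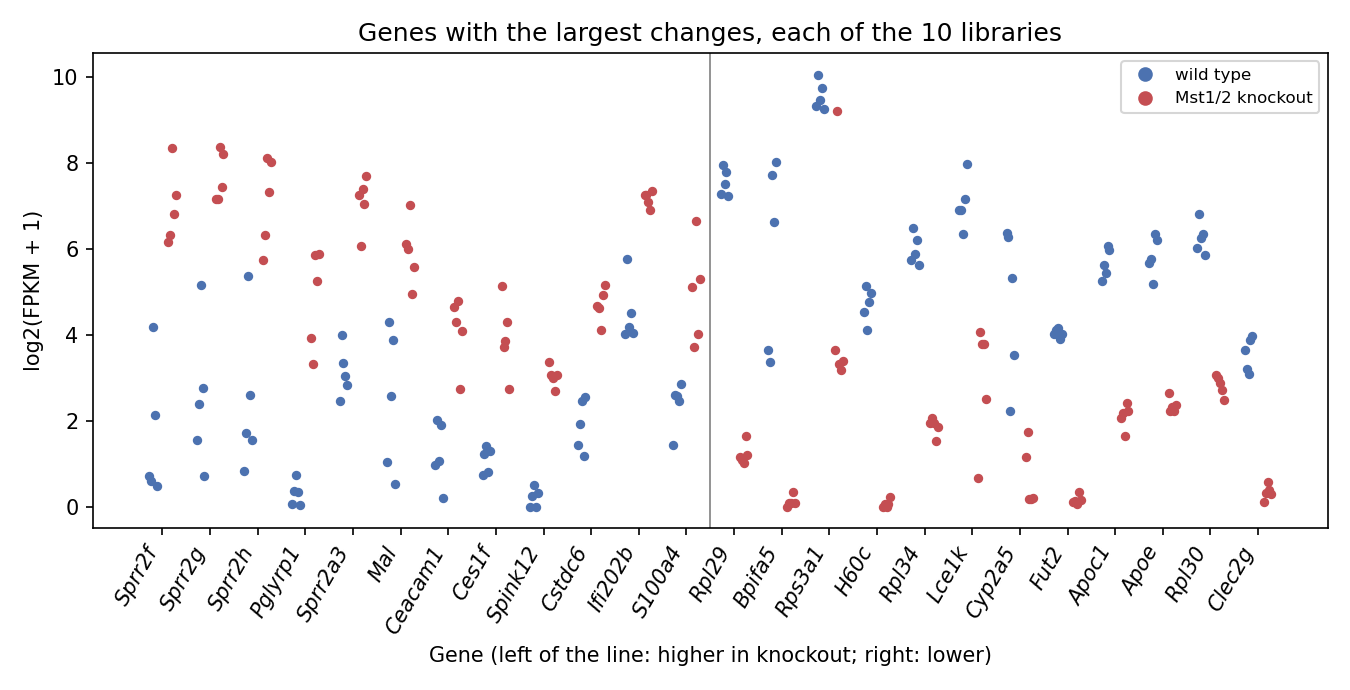
The 12 genes of largest increase (left of the line) and of largest decrease (right) in knockout, as log2(FPKM + 1) in each of 5 wild-type and 5 Mst1/2 knockout libraries (points). The groups do not overlap for any of these 24 genes; Rps3a1 has 1 knockout point, knockout 2 at 590 FPKM, next to the wild-type points.

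**Figure D3:**
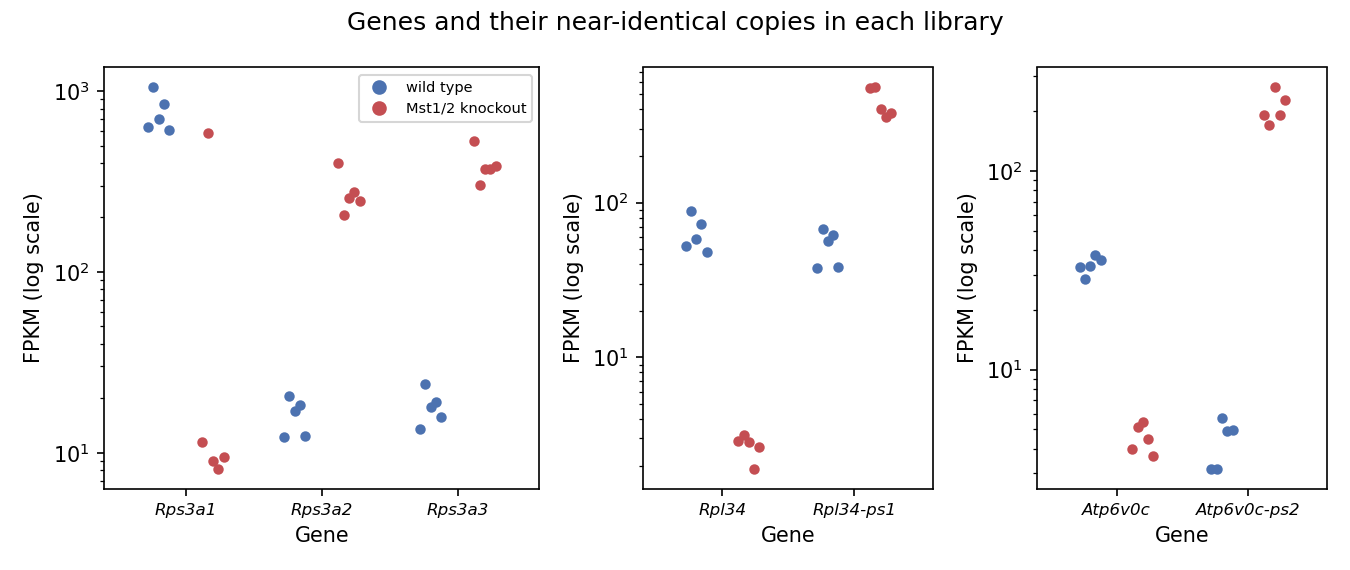
FPKM on a log scale in each library (points) of 3 genes that fell in knockout, Rps3a1, Rpl34 and Atp6v0c, each beside copies of similar sequence that rose. The share of 31-base sequences in common was lowest for Rpl34 and Rpl34-ps1, at 0.364. Rps3a3 went from 18.1 ± 3.96 to 392 ± 85.2 FPKM and Atp6v0c-ps2 from 4.37 ± 1.15 to 210 ± 38.0 FPKM (SD, n = 5 and 5).

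Some cell cycle genes rose in the knockout epithelium. Tyms, which makes thymidylate for DNA synthesis, rose from 1.66 ± 0.431 to 3.91 ± 0.680 FPKM (SD, n = 5 and 5), with a log2 fold change of 0.89 (SE 0.14; limma adjusted p = 0.00164). The replication licensing gene Mcm5 rose from 4.89 ± 3.19 to 12.4 ± 3.75 FPKM, the S-phase cyclin Ccne1 from 1.49 ± 0.456 to 2.96 ± 0.745 FPKM, and Uhrf1, which maintains DNA methylation at replication, from 3.66 ± 2.25 to 8.56 ± 2.71 FPKM. The kinase Melk and the ribonucleotide reductase gene Rrm1 also rose. The proliferation marker Mki67 had 11.7 ± 4.99 FPKM in wild type and 16.8 ± 5.27 FPKM in knockout and did not pass the test (limma adjusted p = 0.264). Of 46 tested proliferation genes, 6 rose over all genes tested and 20 when adjusted over the list alone, none fell, and 45 had a positive fold change, with a median of 0.60 (log2). The list was higher in knockout by limma's camera with a preset correlation (adjusted p = 9.69e-07), but not with the correlation between its genes estimated from the data (adjusted p = 0.764 with an estimated correlation). Camera with the preset correlation called up to 12 lists when the same libraries were split without regard to genotype. Within the libraries of high and of low Dbp, a clock output gene, the mean log2 fold change of the list was 0.57 (3 wild-type and 2 knockout libraries) and 0.46 (2 and 3). With the clock score as covariate the camera adjusted p rose to 0.0437. The mean log2 value of the list overlapped between the groups, at 1.48 to 2.58 in wild type and 2.20 to 3.08 in knockout.

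Some genes of the basal layer fell in knockout. Trp63, the gene of p63, fell from 38.8 ± 5.45 to 22.6 ± 3.58 FPKM (SD, n = 5 and 5), with a log2 fold change of -0.76 (SE 0.13; limma adjusted p = 0.00293). The Cre allele is named for this gene, and whether the allele itself lowers the transcript cannot be separated here from the rest of the genotype. The laminin gene Lama3 fell from 7.31 ± 1.68 to 3.38 ± 1.79 FPKM, and Col17a1, a hemidesmosome collagen, fell from 133 ± 38.1 to 75.8 ± 24.0 FPKM. Pdpn also fell. The basal keratins did not pass the test: Krt5 had 1718 ± 485 FPKM in wild type and 2227 ± 408 FPKM in knockout, Krt14 720 ± 322 and 915 ± 508 FPKM, and Krt15 915 ± 336 and 998 ± 398 FPKM (limma adjusted p = 0.201, 0.643 and 0.849). Of 20 tested basal cell genes, 5 fell over all genes tested and 7 when adjusted over the list alone, and none rose. The list was lower by camera (adjusted p = 0.00427, with a median log2 fold change of -0.22), a call lost with the estimated correlation (adjusted p = 0.764 with an estimated correlation). Its mean log2 fold change was -0.24 within the high-Dbp libraries and -0.14 within the low-Dbp libraries. The score of mesenchymal and muscle markers was lower in the same knockout libraries, by -0.05 on the log2 scale. That score includes the called genes Dcn and Gsn and is no clear measure of tissue composition.

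Squamous differentiation genes moved in both directions. Besides the Sprr2 genes, the cornified envelope precursor Sprr1a rose from 341 ± 68.6 to 1399 ± 635 FPKM (SD, n = 5 and 5; limma adjusted p = 0.00129) and Sprr3 from 4895 ± 1725 to 8574 ± 513 FPKM. The raft protein Mal rose from 7.74 ± 8.03 FPKM (mean 5.06 FPKM without wild type 2) to 67.1 ± 37.3 FPKM and the cysteine proteinase inhibitor Cstb from 217 ± 48.4 to 372 ± 38.7 FPKM. The desmosomal cadherin Dsg1a fell from 190 ± 30.8 to 75.6 ± 13.9 FPKM (limma adjusted p = 0.000273), the calmodulin-like Calm4 from 2175 ± 356 to 836 ± 365 FPKM and the keratin Krt78 from 732 ± 124 to 392 ± 165 FPKM. Involucrin, Ivl, fell from 2.45 ± 1.79 to 0.512 ± 0.432 FPKM. Of 45 tested members, 10 rose, 4 fell and 31 did not pass over all genes tested, and 11 rose and 4 fell when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.236; median log2 fold change 0.22, mean 0.56). Leaving out knockout 1 brought the list past the threshold, at a camera adjusted p of 0.0459, and with a clock score as covariate its direction turned (adjusted p = 0.649); over all alternatives the adjusted p was 0.0459 to 0.807. Its mean log2 fold change was 0.26 within the high-Dbp and 0.64 within the low-Dbp libraries.

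The kinases Mst1 and Mst2 restrain the coactivators YAP and TAZ, so genes that YAP and TAZ activate were a further question of the design. These genes did not move together. The receptor kinase Axl rose from 9.03 ± 2.63 to 15.4 ± 3.90 FPKM (SD, n = 5 and 5; limma adjusted p = 0.0325). Nt5e, the ectoenzyme CD73, fell from 5.96 ± 2.93 to 0.168 ± 0.119 FPKM (limma adjusted p = 0.000209) and F3, tissue factor, from 109 ± 28.3 to 54.4 ± 8.84 FPKM. The target genes Ccn2 and Ccn1 had 1.44 ± 1.03 and 1.16 ± 0.530 FPKM in wild type and 5.50 ± 4.43 and 2.18 ± 1.07 FPKM in knockout, and neither passed (limma adjusted p = 0.0615 and 0.192); without wild type 2, Ccn2 did (adjusted p = 0.0447). Knockout 2 had Ccn2 at 13.2 FPKM, against 2.42 to 5.32 FPKM in the other knockout libraries. Of 21 tested YAP/TAZ target genes, 1 rose and 2 fell over all genes tested, and 3 rose and 2 fell when adjusted over the list alone. Camera gave an adjusted p of 0.347, with a median log2 fold change of -0.09, and leaving out single libraries gave 0.154 to 0.650. The mean log2 fold change of the list differed in sign between the high-Dbp libraries (-0.12) and the low-Dbp libraries (0.08). Among 27 tested Hippo pathway components, Frmd6 fell from 24.3 ± 2.99 to 17.9 ± 1.31 FPKM (limma adjusted p = 0.0229), and it was also the only one past the threshold when adjusted over the list alone. The gene of TAZ, Wwtr1, had 13.2 ± 2.42 and 9.11 ± 2.21 FPKM and did not pass (limma adjusted p = 0.0644), but was past the threshold without wild type 3 (0.0485) or knockout 3 (0.0348). For this list the median log2 fold change, 0.04, and the mean, -0.03, differ in sign, and camera gave the direction of the mean (adjusted p = 0.441).

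**Figure D4:**
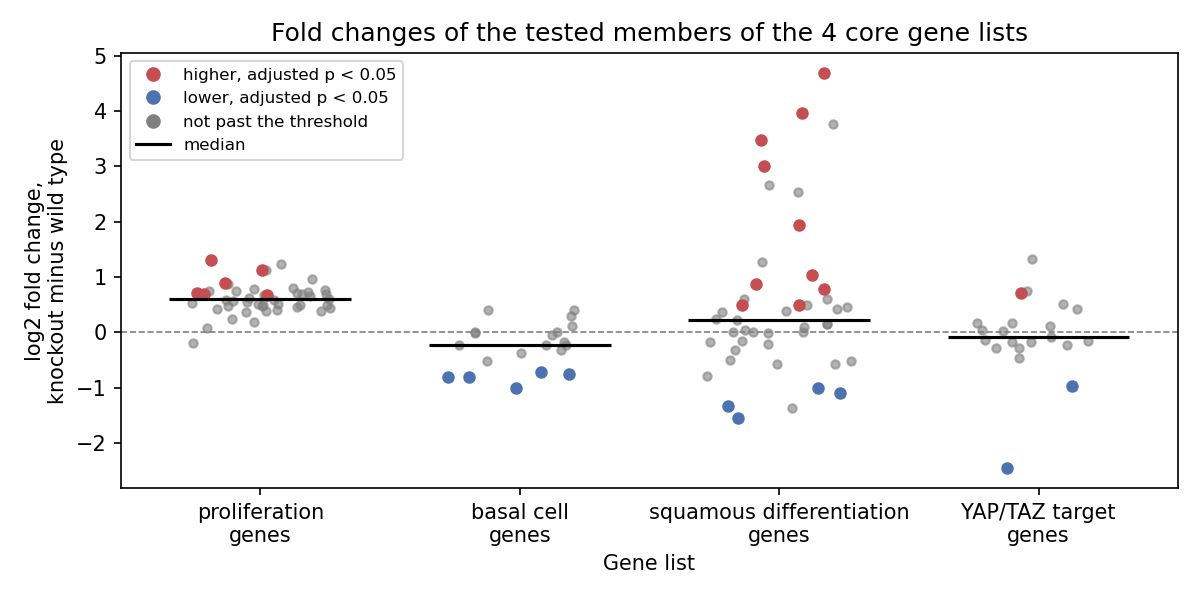
Log2 fold change, knockout minus wild type (vertical axis), of each tested member (points) of the 4 core gene lists, with the median (line); red and blue points are higher and lower at adjusted p under 0.05, and grey points did not pass. Of 46 proliferation genes 45 lie above 0, the 20 basal cell genes have a median of -0.22, and the other lists spread to both sides.

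Some targets of p53 and some stress-induced genes rose in knockout. The receptor gene Eda2r rose from 0.448 ± 0.0630 to 2.27 ± 0.586 FPKM (SD, n = 5 and 5; limma adjusted p = 0.000184) and Ccng1 from 14.7 ± 3.43 to 38.6 ± 9.98 FPKM. Mdm2, the ubiquitin ligase of p53, rose from 7.54 ± 0.827 to 11.2 ± 1.59 FPKM, and Bax, Sesn2, Plk2 and Tnfrsf10b also rose, whereas Perp, a desmosome component, fell from 2356 ± 264 to 1579 ± 122 FPKM and Sesn1 fell. Over the 19 tested p53 targets 7 rose and 2 fell, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.764 with an estimated correlation). With a filter at 5 FPKM the p53 list did not pass (camera adjusted p = 0.201; 4.69e-05 to 0.764 over all alternatives). Of 21 immediate early and heat shock genes, 9 rose, or 11 when adjusted over the list alone, and none fell (camera adjusted p = 0.00228; adjusted p = 0.764 with an estimated correlation). Among them Ier3 rose from 51.8 ± 10.8 to 106 ± 24.7 FPKM, the transcription factor gene Fos from 3.26 ± 1.31 to 11.6 ± 6.61 FPKM, and the chaperone genes Dnajb1 and Hspd1 from 57.0 ± 7.62 to 92.0 ± 12.4 FPKM and from 73.8 ± 12 to 117 ± 11.7 FPKM. Such genes can also respond to handling of the tissue. By fry both the p53 list and the immediate early and heat shock list passed (adjusted p = 0.000932 and 0.0212). By exact permutation neither did (adjusted p = 0.0608 for each), at the smallest p that test can give. None of the 13 mitochondrially encoded transcripts passed singly, by adjustment over all genes or over the list alone, and all 13 had a negative fold change (camera adjusted p = 0.00427; adjusted p = 0.764 with an estimated correlation). The most abundant of those named, mt-Cytb, had 8563 ± 1846 FPKM in wild type and 5505 ± 985 FPKM in knockout (limma adjusted p = 0.0558; 0.0274 without wild type 3).

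Signals to the immune system and growth factor genes changed singly. The alarmin Il33 rose from 104 ± 34.3 to 184 ± 24.5 FPKM (SD, n = 5 and 5; limma adjusted p = 0.0216), the epithelial cytokine Il36g from 197 ± 51.2 to 334 ± 51.5 FPKM and the chemokine Cxcl16 from 1.07 ± 0.35 to 3.37 ± 1.31 FPKM, 3 of 9 tested cytokines and chemokines by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.347). The EGF receptor ligand Hbegf rose from 6.19 ± 1.83 to 24.7 ± 13.5 FPKM (limma adjusted p = 0.00661), and Epgn, Dusp6 and Phlda1 rose too, 4 of 17 by both adjustments, including that adjusted over the list alone (camera adjusted p = 0.935). Of 15 interferon-induced genes 5 rose, or 6 when adjusted over the list alone (camera adjusted p = 0.0542); the antiviral Oas1a went from 1.00 ± 0.706 to 7.45 ± 3.91 FPKM. Knockout 4 stood closer to wild type, with a mean log2 value of the list of 1.70 against 2.18 to 2.84 in the other knockout libraries and 1.34 to 2.04 in wild type; Oas1a was at 2.38 FPKM there and Cxcl16 at 1.37 FPKM. Among 19 wound and stress keratinocyte genes S100a7a rose and Stfa1 fell, with 7 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.935). In that list Krt6a had 280 ± 288 FPKM in wild type and 738 ± 363 FPKM in knockout and did not pass (limma adjusted p = 0.0743), but did without wild type 3 (0.018) or wild type 4 (0.0498).

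Developmental pathway lists held few changes. In the Wnt list the receptor Fzd10 fell from 13.7 ± 3.75 to 5.85 ± 1.25 FPKM (SD, n = 5 and 5; limma adjusted p = 0.00254) and Dkk3 from 4.97 ± 1.61 to 1.75 ± 0.828 FPKM, 2 of 12 tested genes by both adjustments, including that adjusted over the list alone (camera adjusted p = 0.128). Of 16 TGF-beta and BMP targets Id1 rose and Skil and Bmp4 fell, with 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0749). None of 14 Notch pathway genes passed, by limma over all genes or adjusted over the list alone (camera adjusted p = 0.184). Jag1 had 19.8 ± 3.99 and 16.0 ± 2.20 FPKM.

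Among metabolic genes, 6 of 23 cholesterol synthesis genes rose and none fell, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.147). Sqle, squalene epoxidase, rose from 50.1 ± 7.90 to 71.5 ± 6.11 FPKM (SD, n = 5 and 5; limma adjusted p = 0.0152), and Acat2, Nsdhl and Idi1 rose with it. Of 27 antioxidant genes, Gsta1 and the pentose phosphate enzyme gene Tkt rose and Me1 and Hmox1 fell, with 5 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.785). Heme oxygenase, Hmox1, went from 90.5 ± 27.4 to 46.9 ± 12.2 FPKM. In the glycolysis list Eno1 and Pfkm fell, 2 of 20 by both adjustments, including that adjusted over the list alone (camera adjusted p = 0.548). Among 49 cytosolic ribosomal protein genes 1 rose and 5 fell, or 0 and 5 when adjusted over the list alone, with a median log2 fold change of 0.19 and a mean of -0.04 that differ in sign (camera direction up, adjusted p = 0.785). Those that fell include Rpl34 and Rpl30, with log2 fold changes of -4.12 and -3.43. They and other fallen members have copies that rose, so these falls and the list mean are uncertain in how reads were divided between copies. Of the circadian clock list Wee1 rose from 4.45 ± 1.69 to 7.22 ± 0.923 FPKM, 1 of 18 over all genes and none adjusted over the list alone (camera adjusted p = 0.196).

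Markers of other cells were mostly low in this epithelium. Of 214 members of 11 such lists, 172 stayed below 1 FPKM in all libraries. Dcn, a proteoglycan of fibroblasts, fell from 8.59 ± 3.93 to 0.308 ± 0.459 FPKM (SD, n = 5 and 5; mean 0.105 FPKM without knockout 4; limma adjusted p = 8.62e-05) and Gsn, an actin-severing protein that epithelia also express, from 348 ± 82.3 to 212 ± 49.3 FPKM. These were 2 of 5 tested fibroblast markers by both adjustments, including that adjusted over the list alone (camera adjusted p = 0.0862). None of 7 myeloid and Langerhans cell markers and none of 4 Schwann and neural markers passed over all genes (camera adjusted p = 0.935 and 0.518); adjusted over the list alone, 0 and 1 did. For the Schwann and neural list the median log2 fold change, -0.20, and the mean, 0.14, differ in sign, and camera gave the direction of the median. Lists with fewer than 3 tested members were not tested. Their most abundant members, by mean over all libraries, were Flt1 for endothelium (1.13 FPKM), Smtn for smooth muscle (3.62 FPKM), Tnni2 for skeletal muscle (4.84 FPKM), Cd5 for lymphocytes (5.99 FPKM), Cxcr2 for granulocytes and mast cells (3.86 FPKM), Krt20 for stomach and columnar cells (0.906 FPKM), Lipe for blood and adipocytes (6.94 FPKM) and Tppp3 for trachea and thyroid (83.3 FPKM). The Krt20 mean rests mostly on knockout 3, at 6.51 FPKM, against at most 0.79 FPKM in the other libraries. Eif2s3y was the most abundant of the sex-linked transcripts, at 20.4 FPKM.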

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

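The tests on genes that single knockout libraries keep near the wild-type level were all chosen after the results were seen. Each named gene was looked at within its group of 5 libraries for a single value lying far from the other 4, and chance alone gives such a value in about 5% of groups. Here 19 of 322 groups had one, but this share cannot be set against chance, since Eif3j1, Capza1, Ces1b and Il15 were named because 1 library stood apart.

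Knockout 2 stood apart for several genes that the other knockout libraries had nearly lost or had lower. Rps3a1 was at 590 FPKM there against 8.08 to 11.4 FPKM in the others, Capza1 at 22.4 FPKM against 7.99 to 10.8, Ces1b at 103 FPKM against 21 to 28.3 and Il15 at 1.22 FPKM against 0 to 0.13. Sprr2a1 rose from a mean of 8.45 FPKM in wild type to 21.1 FPKM in the other knockout libraries. In knockout 2 it was at 10.3 FPKM. Rps3a1, Capza1 and Sprr2a1 lie on chromosome 3, and Ces1b and Il15 on chromosome 8. In knockout 1, Eif3j1 was at 3.53 FPKM against 0.30 to 0.41 FPKM. Wild-type tissue or RNA mixed into knockout 2 would pull all changed genes toward wild type, but the median position of its 112 most clearly changed genes, on a scale from wild type (0) to the other knockout libraries (1), was 0.953 (quartiles 0.809 to 1.09). Strain variants that segregate among the knockout mice may account for part of the pattern in knockout 2, where genes kept near the wild-type level shared a chromosome more often than chance gives (22 pairs against 6.58 expected; permutation test, p = 2e-04); the excess over all 5 libraries (33 pairs against 16.3, p = 0.001) rests on knockout 2, as none of the other 4 passed (p = 0.13 to 1). Variants carried along with the modified Stk4 allele could also add to the calls, as 50% of the 20 tested neighbours of Stk4 were called (99.8th percentile of all genes), against a median of 10.0%. For Stk3 it was 30% (94.2nd percentile) and for Trp63 15% (52.8th percentile). Both leave open that loss of the kinases itself changed these genes, which was not tested apart from genetic background.

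The other single values, given without explanation, were these. Among knockout libraries, Stk4 was at 12.2 FPKM in knockout 3 (15.8 to 17.4 in the others), S100a7a at 268 FPKM in knockout 2 (205 to 222), Jag1 at 12.2 FPKM in knockout 5 (16.2 to 17.8), Bpifa5 at 0.27 FPKM in knockout 4 (0 to 0.07), Dcn at 1.12 FPKM in knockout 4 (0.06 to 0.22) and Krt20 at 6.51 FPKM in knockout 3 (0.23 to 0.79). Among wild-type libraries, Ifi202b was at 53 FPKM in wild type 2 (15.2 to 21.7), Ddx3y at 26.1 FPKM in wild type 2 (15.6 to 17.6), Capza1 at 35.8 FPKM in wild type 2 (24.6 to 27.1) and S100a4 at 1.70 FPKM in wild type 1 (4.49 to 6.25). Wild type 1 had Tppp3 at 32.4 FPKM (76.2 to 103), and wild type 3 had Nsdhl at 32.6 FPKM (24.8 to 26.8), Krt20 at 0.65 FPKM (0 to 0.11) and a mean log2 value of the glycolysis genes of 4.92 (4.66 to 4.71).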

How the results depend on the processing

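Of these tests, the clock covariate and the exclusion of genes sharing sequence were chosen after the results were seen. No called gene changed sign under any setting that was run, and Stk3 stayed past the threshold wherever it was tested (log2 fold change -1.72 to -1.58 over left-out libraries; not tested with a filter at 5 FPKM, which removes it), while Stk4 never passed (-0.33 to -0.21 over left-out libraries). Higher and lower genes, 900 and 565 as reported, numbered 293 and 245 at adjusted p under 0.01, 1533 and 887 under 0.10, and 171 and 183 with an absolute log2 fold change of at least 1. Without a filter there were 511 and 466, as more low genes were tested, and with a filter at 5 FPKM 686 and 329, as fewer were. Sample quality weights gave 1390 and 787, and the cause was not tested. With the marker score as covariate 179 were higher and 181 lower. The score includes the called genes Dcn and Gsn, so it can take up part of the genotype difference. Of the 1465 calls 340 then remained, and all kept their sign: the median absolute log2 fold change went from 0.65 to 0.56 and the median SE from 0.14 to 0.18, and the score correlates with genotype (-0.66). Leaving out single libraries gave 436 to 1091 higher and 357 to 679 lower genes, with fewer libraries in each fit. Counts moved by over 1.5 times without wild type 1 (495 and 363), wild type 5 (436 and 357), knockout 1 (538 higher), knockout 3 (572 higher) and knockout 5 (529 and 369). All 1188 called genes that could be tested without sequence sharing were kept. Leaving out other genes hardly changes the test of a gene that stays, so this says nothing on how reads were divided between copies. Rpl34 and Rpl30, which have copies of similar sequence, share less than 0.2 and stayed in.

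Camera called 3 lists higher and 2 lower. The numbers were 0 and 0 with an estimated correlation and by the exact permutation test, and fry gave 2 and 0. The 2 lists were the p53 targets and the immediate early and heat shock genes (fry adjusted p = 0.000932 and 0.0212). The p53, immediate early and fibroblast lists were at the smallest p that the permutation test can give (0.0079; adjusted p = 0.0608), so for them it says nothing on stability. No filter gave 5 and 2, the marker score 5 and 3, the Y gene score 4 and 5 and the clock score 5 and 4; leaving out libraries gave 3 to 4 higher and 2 to 4 lower, with 4 lower without wild type 2 and without knockout 5. The adjusted p of the basal and proliferation lists was 0.764 and 0.764 with an estimated correlation, 0.166 and 0.152 by fry, and 0.183 and 0.183 by exact permutation; over left-out libraries it was 0.00104 to 0.0376 and 8.68e-11 to 0.000163. The squamous list turned to the lower side with the clock score (0.649), and passed without knockout 1 (0.0459), with 0.0459 to 0.610 over left-out libraries. Of genes that did not pass, the log2 fold change of Krt14 turned to -0.07 with the clock score, that of Krt15 to -0.06 and of Jag1 to 0.01 with the marker score, and Krt15 ranged from -0.07 to 0.29 over left-out libraries. Except where stated, the cause was not tested.

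The replicate numbers do not pair the libraries: the deviations of same-numbered libraries correlated at 0.06, 0.42, 0.19, -0.24 and 0.11, and 1 of 5 matched its own number best. With the number as a replicate block limma gave 773 higher and 551 lower genes, and camera 4 higher and 4 lower lists. At 13050000 to 16460000 fragments per library, values such as the 0.05 to 0.25 FPKM of Stk3 in knockout rest on 57 fragments over the 5 libraries.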

Other observations

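The gene lists in the next paragraph, the tests on gene copies and the covariate for clock genes were chosen after the results were seen; the tests on other splits of the libraries and on the share of calls kept with that covariate were written before their results.

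Some genes of the secretory pathway rose in the knockout epithelium. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 122 ± 20.5 to 239 ± 57.7 FPKM (SD, n = 5 and 5; limma adjusted p = 0.00785), its partner Hsp90b1 from 86.8 ± 9.53 to 160 ± 34.8 FPKM, Creld2 from 17.4 ± 1.91 to 34.2 ± 8.31 FPKM and the transcription factor gene Xbp1 from 70.9 ± 10.9 to 97.9 ± 11 FPKM. Knockout 3 stood closer to wild type, with Hspa5 at 146 FPKM, inside the wild-type range of 103 to 151 FPKM, Hsp90b1 at 106 FPKM and Creld2 at 23.1 FPKM. Of 40 such chaperone and translocon genes 23 rose, and 1, the pseudokinase gene Trib3, fell from 5.44 ± 1.79 to 2.32 ± 0.472 FPKM, while the others did not pass (camera adjusted p = 2.54e-08; adjusted p = 0.107 with an estimated correlation). Of 36 ribosome biogenesis genes 13 rose and none fell (camera adjusted p = 1.08e-08; adjusted p = 0.212 with an estimated correlation). These included the methyltransferase gene Fbl, from 7.0 ± 0.811 to 10.5 ± 1.52 FPKM, and Npm1, from 154 ± 35.0 to 228 ± 35.9 FPKM.

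Some cell junction and cornification genes changed, in both directions. The connexin Gjb5 fell from 23.5 ± 0.927 to 8.66 ± 0.997 FPKM (SD, n = 5 and 5; limma adjusted p = 1.92e-06), and the tight junction gene Cldn1 from 13.0 ± 4.09 to 5.15 ± 2.73 FPKM, while Cldn4 rose from 49.9 ± 3.70 to 70.6 ± 15.7 FPKM. Of 20 gap junction, tight junction and desmosome genes 5 fell and 1 rose (camera adjusted p = 0.000321; adjusted p = 0.0801 with an estimated correlation). Of 21 late cornified envelope (Lce) genes 6 fell, all of the Lce1 group, with Lce1c from 608 ± 182 to 216 ± 143 FPKM (camera adjusted p = 2.17e-05; adjusted p = 0.226 with an estimated correlation), whereas 7 of 15 Sprr genes rose and none fell (camera adjusted p = 2.54e-08; adjusted p = 0.107 with an estimated correlation). No gene of the Lce3 group passed the test, so the fall does not cover the whole Lce family. The desquamation proteinase genes Klk5 and Klk7 fell from 15.7 ± 3.87 to 2.64 ± 3.20 FPKM and from 69.8 ± 16.9 to 22.7 ± 14.7 FPKM; without knockout 4 the knockout mean of Klk5 was 1.32 FPKM. These lists were drawn up from genes seen to change, so their p-values are not independent evidence.

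Several genes fell while copies of similar sequence rose. Pairs were taken as sharing sequence from a share of 0.2 of 31-base sequences, so not all are near-identical. Of 45 pairs of changed genes that share sequence and both have an absolute log2 fold change of at least 1, 22 went in opposite directions, 21 of them on different chromosomes. A wrong placement of spliced reads on unspliced copies in the knockout libraries alone would lower parent genes in general, but 47 of 1101 tested parents of pseudogenes were lower (a share of 0.0427) and 106 higher. Reads of a parent sequence that differs between the mice may instead be assigned to its copies: in the knockout library that keeps a parent near the wild-type level, 6 of 6 risen copies (a share of 1) had their lowest knockout value, against 0.2 by chance, for Eif3j1 in knockout 1 and for Tpm3, Rps3a1 and Capza1 in knockout 2. Copies of one parent are not independent, and a real change of the parents stays open.

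Libraries differed in clock output genes. Dbp lay between 8.45 and 22.6 FPKM in wild type 1, 2 and 4 and knockout 1 and 2, and between 0.38 and 1.73 FPKM in the other 5. If the hour of collection were the cause of the called differences, few calls should stay with a clock score as covariate, but 1028 of 1465 genes did (a share of 0.702). Within the high-Dbp libraries limma called 206 genes higher and 230 lower, and within the low-Dbp libraries 203 and 181. The other calls were lost with that covariate, and a part played by collection time in the called differences stays open.

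Other splits of the libraries did not reach the gene counts: of 100 of the 126 splits of the libraries into 5 and 5, only the real one (1 of 100 in each direction) gave as many as 900 higher or 565 lower genes, and the highest of the others gave 1 in each direction. That is the smallest share this test can give. The other splits mix genotypes, which adds the genotype difference to their spread, and the libraries are not stated to be separate mice. Chance is thus made unlikely but is not excluded. For the list calls the real split did not stand out: it gave 5 lists, 64 of 100 splits gave at least as many, and the highest other gave 12.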
